A study of Mus musculus with 6 samples.

How the data were processed

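The series holds RNA sequencing of ear skin from 3 WT mice and 3 HdR mice, all treated with imiquimod and sampled on day 1. Per the labels, total RNA was extracted with TRIzol and RNeasy columns, libraries were made with the NEBNext Ultra II RNA kit and sequencing was done on a NovaSeq instrument. The submitters' processing notes give the genome build as GRCm38. The aligner, the counting program, the gene annotation, the strandedness and the method of RNA selection are not given in the sources used here. The genotype label HdR was read, from the series' design text, as HOIL1 without its RING1 domain.

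The deposited table holds coverage, a signal summed as aligned bases per gene, for 23518 gene symbols in 6 columns, and the authors' own steps between reads and these sums are not given in the sources used here. The values are whole numbers that gather at multiples of 300, the length of a read pair with 150-base reads: 1656 values equal 300 exactly, and 10.3% of the low values are whole multiples of 300, against 0.333% by chance. The values are therefore not counts of reads, and the count test of the design was replaced by the fallback stated there, limma with an intensity-dependent prior variance on log2 values.

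Columns were scaled with the trimmed mean of M values (30% of log ratios and 5% of intensities trimmed), which gave factors of 1.15, 1.02 and 1.19 for WT and 0.931, 0.792 and 0.973 for HdR, and expressed as bases per Mb of effective library size. Depth was 5038, 5658 and 5966 Mb in WT replicates 1 to 3 and 5264, 4433 and 4472 Mb in HdR replicates 1 to 3, so that 1 base per Mb stands for 11.7 to 23.6 read pairs per library. A value of 0 was held by 229 genes in all libraries. The 15049 genes with at least 1 base per Mb in at least 3 libraries were tested on log2(value + 1) with robust limma-trend (R 4.3.3, limma 3.58.1), HdR against WT without covariates, two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Adjusted p values given for genes in the report come from limma, and those for lists from camera in limma with Benjamini-Hochberg adjustment over the lists. Each limma p value measures the spread between these 3 and 3 samples. Camera p values with the preset correlation rest mainly on the spread between genes, and the Fisher exact p value rests on counts of genes. Length and composition of the libraries were compared with exact permutation tests of all 3 and 3 splits. Pairwise r of replicates on the log2 scale ran from 0.961 to 0.989, and the leading principal component carried 73.4% of the variance and the next 10.4%.

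Before the data were examined, the samples, the tests, the alternatives, the rule for naming genes and 30 gene lists were fixed. The rule names Rbck1, Rnf31 and Sharpin, the 12 largest log2 changes in each direction among genes with an adjusted p under 0.05, no overlap between the genotypes and a mean of at least 1 base per Mb (gene models Gm with digits, Rik names and pseudogenes left out), and up to 4 genes with the smallest p from each list. The lists were LUBAC and linear ubiquitin regulators, TNF and NF-kB target genes, IL-23 and IL-17 axis, chemokines, wound and stress keratinocyte genes, cornified envelope and late differentiation, basal keratinocyte, hair follicle and hair shaft, sebaceous gland, type I interferon response, interferon gamma response and antigen presentation, neutrophils, monocytes and macrophages, dendritic and Langerhans cells, T and NK cells, B cells, mast cells and basophils, eosinophils and type 2 cytokines, fibroblasts and matrix, endothelium, skeletal muscle, adipocytes, cartilage, Schwann cells and melanocytes, cell cycle, cell death regulators, immediate early and heat shock genes, blood, mitochondrially encoded genes and sex-linked genes. Camera was run with a preset correlation of 0.01 on the 27 lists with at least 5 genes tested. Genes of a list were also adjusted over that list alone.

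Alternatives fixed beforehand were median-of-ratios, total and quantile scaling, voom with sample quality weights, no filter, a filter on at least 1 base per Mb in at least 3 libraries, a pseudocount of 0.1, the replicate number as a block, a threshold of 0.1, each library left out in turn, an estimated correlation between genes, camera on ranks and fry. Alternatives added after seeing the data were the removal from each library of a natural spline (4 degrees of freedom) on log2 transcript length, alone and together with the replicate block or without HdR replicate 2, and a filter at 5 bases per Mb. Lengths and coordinates were those of the longest transcript and the gene in GENCODE M21 on GRCm38, which held 23087 of the 23518 symbols and gave a length to 99.0% of the genes tested. The longest transcript need not be the one expressed, so corrected values of single genes depend on this choice.

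The labels do not say whether replicate numbers pair the mice. After removal of genotype means, HdR and WT libraries of the same number correlated at 0.163, 0.416 and 0.366 (0.133, 0.320 and 0.286 with the length trend removed) and those of different numbers at -0.378 to 0.159, so that by the rule fixed for this check (all above 0.1) the numbers were treated as pairs in an alternative with a replicate block.

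The procedure was tested on simulated data with the depths and mean levels of the real libraries, a dispersion of 0.04 and 200 changed genes. It recovered 70% of the 2-fold and 100% of the 4-fold changes, and 11 unchanged genes made up 6.08% of the calls. With a simulated length trend 752 unchanged genes made up 81.0% of the calls, and after its removal 11 made up 6.15%. In these runs 0 lists without changed genes were called. Each gene was drawn independently, so the runs cannot show how often camera calls lists whose genes vary together. The trend was simulated on the same lengths that its removal used, with the same slope in all libraries of a genotype. Changed genes were picked without regard to length. The runs thus do not show how well the removal works on the real libraries, or whether it spares real changes that go with length. Read-level files were not analysed here, so exons, strands and splice forms were not examined. Genes of close copies, such as the Sprr2, Lce, Stfa and keratin families and Lyz1 with Lyz2, may share reads in these sums.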

Results

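RNA from mouse ear skin was sequenced 1 day after treatment with imiquimod, a Toll-like receptor agonist whose cream induces psoriasis-like inflammation in mouse skin. The ears received 10 mg of a cream with 5% imiquimod. The 6 samples form 2 genotypes of 3 samples each, wild type (WT) and HdR, the label for mice whose HOIL1 protein lacks its RING1 domain. HOIL1 (also HOIL-1L) is the product of Rbck1 and forms the linear ubiquitin chain assembly complex, LUBAC, with HOIP and SHARPIN. All samples were treated, so the comparison of HdR with WT asks how the genotype alters skin transcript levels under imiquimod, and it says nothing about skin without imiquimod. The deposited values were sums of aligned bases per gene for 23518 genes. They totalled 5038, 5658 and 5966 Mb in WT replicates 1, 2 and 3 and 5264, 4433 and 4472 Mb in HdR replicates 1, 2 and 3, equal to 14.8 to 19.9 M read pairs of 300 bases. Levels below are normalised coverage in bases per Mb of aligned sequence as mean ± SD (n = 3 per genotype), and changes are HdR minus WT on the scale of log2(value + 1), which understates the change of low genes.

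Rbck1 (ENSMUSG00000027466.15; chromosome 2, positions 152316334 to 152332653 of GRCm38, minus strand) was lower in every HdR sample. Its coverage was 66.6, 55.1 and 64.1 in the WT samples and 23.9, 13 and 19.7 in the HdR samples, a log2 change of -1.70 (SE 0.22; limma, Benjamini-Hochberg adjusted p = 0.00438) and of -1.74 with the length trend described below removed. A sum over the whole gene cannot show which exons lost reads, so this value does not show the deletion itself. Rnf31 (ENSMUSG00000047098.18; chromosome 14, 55591708 to 55603693), which encodes HOIP, the catalytic subunit of LUBAC, read 20.6, 10.8 and 25.1 in WT and 7.96, 5.06 and 9.43 in HdR (log2 change -1.18, limma adjusted p = 0.0271). With the length trend removed the Rnf31 change was -0.80 and no longer passed (limma adjusted p = 0.0609). Sharpin (ENSMUSG00000022552.16; chromosome 15, 76347040 to 76351111) stood at 24.2 ± 3.13 in WT and 31.0 ± 3.54 in HdR and did not pass (log2 change 0.35, limma adjusted p = 0.141).

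Part of the NF-kB target genes, chemokines, genes of the IL-23 and IL-17 axis and markers of neutrophils and macrophages had higher coverage in HdR skin than in WT skin, while most hair follicle keratins and many type I interferon response and cell cycle genes had lower coverage. As lists they passed camera with a preset correlation, and none did with an estimated correlation (adjusted p = 0.384 to 0.561). Of 35 NF-kB targets 15 rose, of 29 chemokines 16, of 22 genes of the IL-23 and IL-17 axis 10, of 18 neutrophil genes 8 and of 24 macrophage genes 12. The NF-kB, chemokine and IL-23 and IL-17 lists share members, so their counts are not independent. Of 31 hair follicle genes 29 fell, of 38 type I interferon genes 21 and of 35 cell cycle genes 19. Nfkbia, the gene of the NF-kB inhibitor IkBa and itself an NF-kB target, rose from 124 ± 26 to 337 ± 25.2, and Oasl2, an antiviral gene of the interferon response, fell from 166 ± 24.3 to 55.0 ± 7.83. The adipocyte genes Fabp4 and Adipoq rose and the collagen gene Col1a1 fell.

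**Figure D1:**
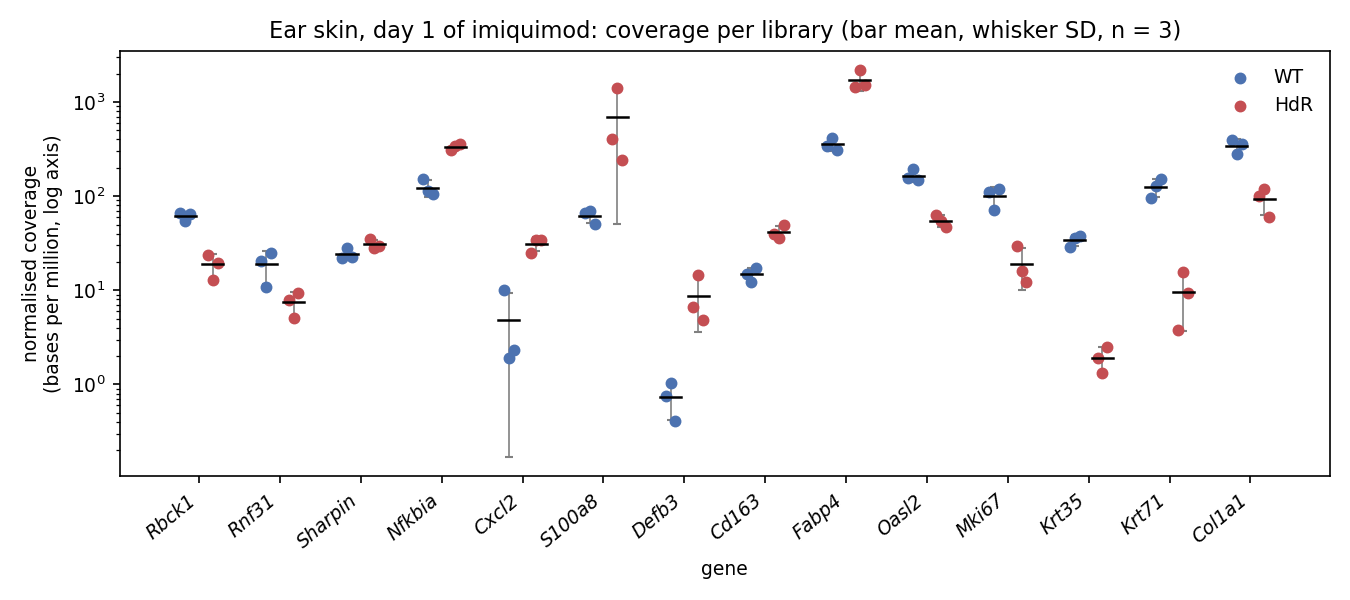
Normalised coverage (bases per Mb, log axis) of 14 genes in each library; points are single libraries, bars means and whiskers SD (n = 3 per genotype). Rbck1 in HdR lies between 13 and 23.9, below its lowest WT value of 55.1, and Sharpin in HdR starts at 28.4, just above its highest WT value of 27.8.

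The limma test called 4605 of 15049 genes changed at an adjusted p under 0.05 (30.6%), 1904 higher and 2701 lower in HdR, of which 702 were more than 2-fold higher and 963 more than 2-fold lower. In 51.5% of the tested genes the 3 values of one genotype all lay on one side of the 3 of the other, against 10% by chance. With the replicate number as a block, 4094 genes were lower and 2749 higher. The median change of all tested genes was -0.13. It was -0.41 with scaling to total bases, where 917 genes were higher and 4305 lower (17.6% of calls higher, against 41.3%). It was -0.01 with quantile normalisation, with 2362 higher and 2084 lower (53.1% higher). The number of calls was 427 without WT replicate 1, 1353 without WT replicate 3, 1912 without HdR replicate 2 and 2812 without HdR replicate 1.

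Transcript length moved with the genotypes. Among the shortest 10% of transcripts (up to 1289 nt) 732 genes were higher and 77 lower in HdR, with a median change of 0.63, and among the longest (from 6642 nt) 26 were higher and 651 lower, with a median of -0.58. Slopes on log2 transcript length were fitted to each gene's log2 deviation from its mean over all libraries. They were 0.190, 0.0404 and 0.247 per doubling of length in the WT libraries and -0.125, -0.272 and -0.0805 in the HdR libraries (exact permutation p = 0.1, two-sided, the smallest that 3 against 3 samples allow). The opposite signs follow from this centring, so the slopes show only how libraries differ from each other. The leading principal component, with 73.4% of the variance, ranked the libraries in the order of these slopes, within each genotype too. On it WT replicates 1, 2 and 3 stood at -45.4, -14.3 and -59.9 and HdR replicates 1, 2 and 3 at 29.1, 63.8 and 26.7. Genotype and length trend thus cannot be told apart on this component. The 45S ribosomal RNA precursor Rn45s took 0.112% ± 0.00856 of all bases in WT and 1.04% ± 0.603 in HdR, and the 10 most covered genes took 4.63% ± 0.631 and 7.74% ± 1.70 (exact permutation p = 0.1 for each). With a length trend removed from each library, an alternative chosen after seeing the data, limma called 2884 genes, 1621 higher and 1263 lower. Of these, 2190 were called in the same direction without the correction and 0 in the opposite direction. Values with this correction are given beside the gene groups.

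**Figure D2:**
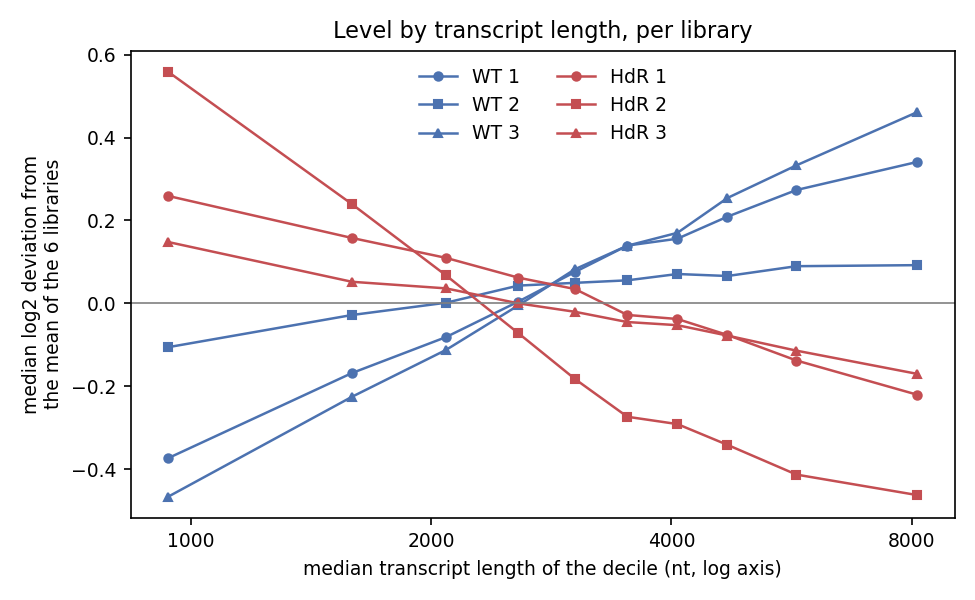
Median log2 deviation from the mean of the 6 libraries in 10 bins of transcript length (x axis: median length of the bin in nt, log axis), 1 line per library. The 3 HdR lines run downward with slopes from -0.272 to -0.0805 and the 3 WT lines upward from 0.0404 to 0.247; WT replicate 2 lies nearest to the HdR libraries.

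Among the 12 genes with the largest rise were 3 structural or ribosomal non-coding RNAs: Rpph1, the RNA of RNase P (log2 change 3.39), Rmrp, the RNA of RNase MRP (3.34), and Rn45s (3.30). Their HdR samples were uneven: replicates 1, 2 and 3 read 3.46, 40.2 and 19.0 for Rpph1, 3.83, 35.1 and 15 for Rmrp and 3958, 19414 and 12451 for Rn45s. Without HdR replicate 2 the log2 change of Rn45s was 2.81, and those of S100a8 and S100a9 were 2.34 and 2.36. S100a8 and S100a9, whose proteins form the antimicrobial complex calprotectin, lie side by side on chromosome 3 (90668978 to 90670035 and 90692632 to 90695721). They rose from 61.7 ± 9.94 to 690 ± 639 and from 90.0 ± 17.5 to 878 ± 722, with HdR replicate 2 at 1421 and 1709 and the other HdR samples between 244 and 531. The neutrophil chemoattractant Cxcl2 (log2 change 2.75), the B cell chemoattractant Cxcl13 (2.49), the neutrophil-associated Retnlg (2.62), the lysozyme gene Lyz1 (2.45), the beta-defensin Defb3 (2.38), the methyltransferase Inmt (2.34) and Mucl1 (3.22) made up the rest. Lyz1 stood at 42.0 ± 11.1 in WT and 228 ± 4.88 in HdR (limma adjusted p = 0.00113). All of these passed again with the length trend removed, with changes from 1.68 for Defb3 to 2.70 for Rpph1, except Rn45s, which had no annotated length.

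Hair keratins led the genes that fell. Krt71, Krt72 and Krt73, keratins of the inner root sheath of the hair follicle, lie within positions 101733949 to 101802346 of chromosome 15 and fell, with log2 changes of -3.72, -3.31 and -3.86. Krt25, Krt26 and Krt28, on chromosome 11 between 99315516 and 99374903 and also expressed in the inner root sheath, fell, with changes of -3.29, -3.66 and -3.46, and the hair shaft keratin Krt35 (chromosome 11, 100092193 to 100096241) fell from 34.1 ± 4.73 to 1.91 ± 0.573 (limma adjusted p = 3.03e-04). The hair keratin-associated gene Krtap15 (-3.41), the cornified envelope gene Crnn (-3.48), the lysozyme-like Lyg2 (-3.60), Calhm4 (-3.71) and Tsix (-3.37) fell as well. With the length trend removed these 12 changes ran from -3.96 to -3.05. Tsix (chromosome X, 103431517 to 103484957) overlaps its antisense partner Xist, the RNA that silences 1 X chromosome, and without a stated strand their reads cannot be told apart. Xist fell from 1363 ± 346 to 375 ± 137 (log2 change -1.90; -1.30 with the length trend removed). Both are members of the sex-linked list, in which 2 genes were tested.

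The camera test, which compares a list with all other genes, was run on 27 lists fixed before the data were examined. It passed 17 of them, 13 higher and 4 lower, and 12 with the length trend removed, 11 of them in both. With a correlation between genes estimated from these samples, camera passed 0 lists, the smallest adjusted p being 0.384 and the unadjusted p lying under 0.05 for 2 lists. After length correction it passed none either (smallest adjusted p = 0.525). The rotation test fry, which asks only whether a list's own genes move one way, passed 4, namely the hair follicle, adipocyte, IL-23 and IL-17 and Schwann cell and melanocyte lists. Other splits of the 6 libraries into 3 and 3 also passed 8 to 16 lists by camera with the preset correlation. Total scaling moved the list medians by -0.32 to -0.10. Where 5 or fewer members of a list moved in a direction, those outside the fixed rule for naming genes are named too, a choice made after their values were seen.

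**Figure D3:**
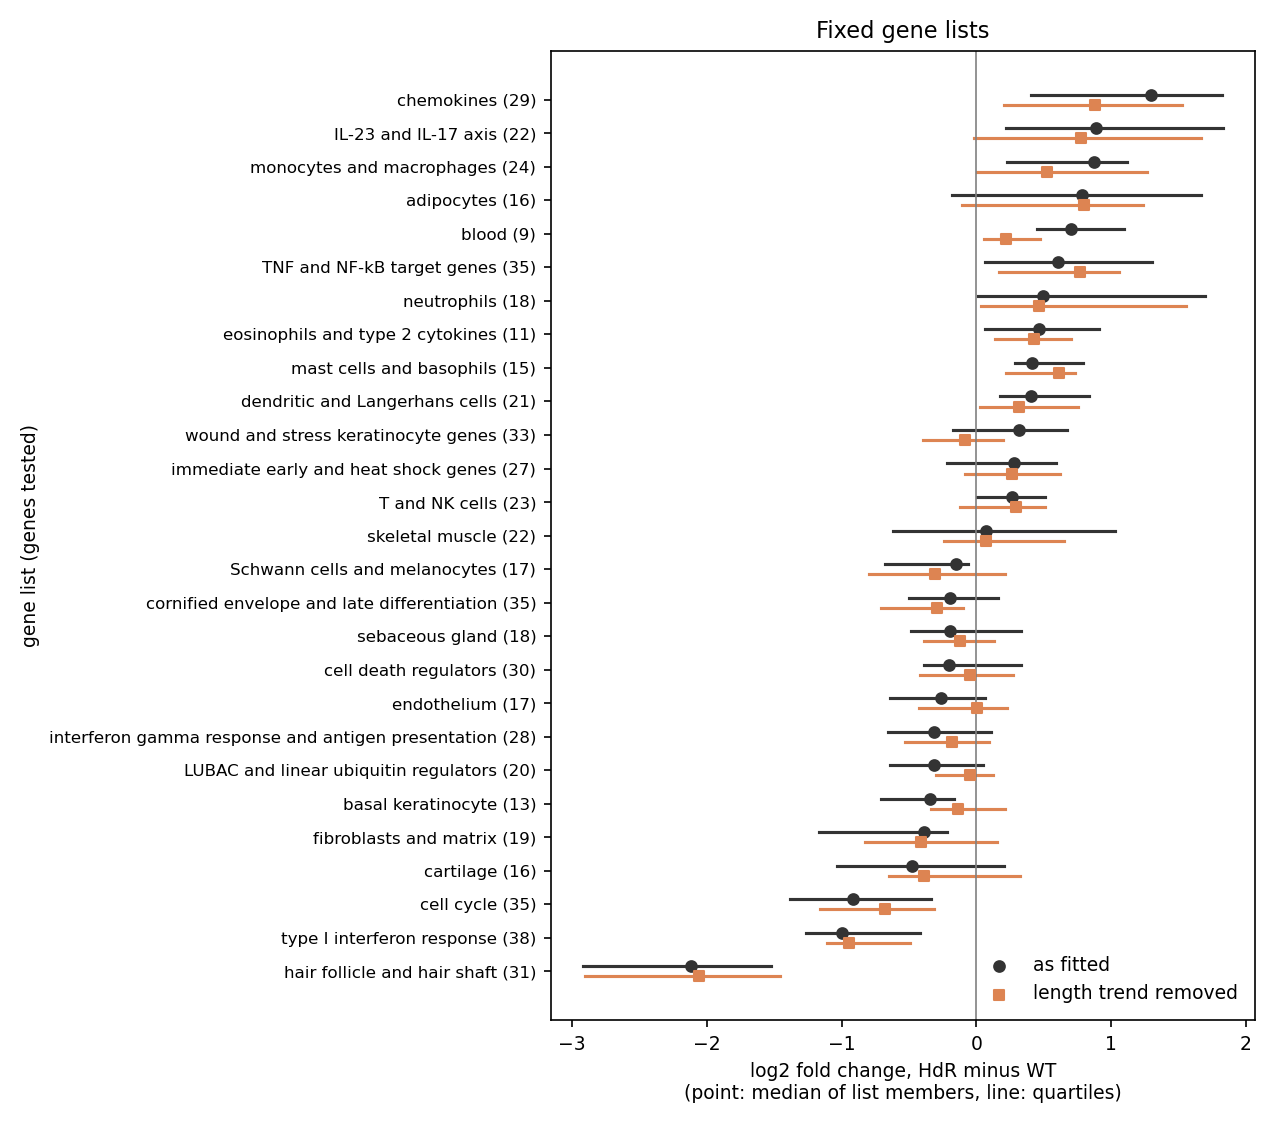
Log2 change, HdR minus WT, of the 27 lists tested (y axis, genes tested in brackets); points are medians of list members and lines their quartiles, as fitted (black circles) and with the length trend removed (orange squares). The hair follicle list lies lowest, at -2.12 and -2.06, and the chemokines highest, at 1.29 and 0.88; the wound and stress list moves from 0.32 to -0.08.

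Part of the NF-kB targets, of the genes of the IL-23 and IL-17 axis and of the chemokines were higher in HdR. These lists share members, so their results are not independent. Cxcl1 and Ccl20 are in all of them, and Cxcl2, Ccl2, Ccl7 and Cxcl10 are in both the NF-kB and chemokine lists. Of 35 NF-kB targets tested, 15 rose and Rel fell by 0.85 (16 and 1 adjusted over the list alone), with a median log2 change of 0.61 (camera adjusted p = 1.04e-05, and adjusted p = 0.543 with an estimated correlation). Ier3 rose from 51.6 ± 12.2 to 133 ± 9.10 and the cytokine gene Il6 from 1.63 ± 0.775 to 9.74 ± 3.59. With total scaling 8 rose (median 0.31). With the length trend removed 16 rose and 0 fell (median 0.77, camera adjusted p = 1.90e-05). Of 22 genes of the IL-23 and IL-17 axis, the cytokine pathway of psoriasis, 10 rose and 3 fell (12 and 3 adjusted over the list alone; median 0.89, camera adjusted p = 1.11e-04, and adjusted p = 0.384 with an estimated correlation). The beta-defensin Defb14 rose from 9.02 ± 3.56 to 36.0 ± 18.2, and the members that fell were the receptor genes Il22ra1 (-0.94), Il17rc (-1.04) and Il17ra (-0.64). The length correction gave 10 higher and 2 lower (median 0.77, camera adjusted p = 0.00656). Of 29 chemokines 16 rose and 0 fell (17 and 0 adjusted over the list alone; median 1.29, camera adjusted p = 2.80e-07, and adjusted p = 0.535 with an estimated correlation). Among them Ccl27a, a chemokine of keratinocytes that attracts skin T cells, rose from 14.5 ± 2.99 to 46.1 ± 12.2, and Ccl17 from 22.3 ± 12 to 94.9 ± 29.1. After length correction 14 chemokines rose (median 0.88, camera adjusted p = 5.50e-04). Without WT replicate 1 the counts of risen genes were 8 NF-kB targets, 5 genes of the IL-23 and IL-17 axis and 6 chemokines. They were 8, 5 and 5 without HdR replicate 2. Without WT replicate 3, 9 NF-kB targets and 6 genes of the IL axis rose, and without HdR replicate 1, 10 chemokines did. The median of the IL axis was 0.58 without WT replicate 3 or HdR replicate 2, 0.59 without HdR replicate 1 and 0.39 with the filter at 5 bases per Mb, and 0 of its genes fell without WT replicate 1, WT replicate 3 or HdR replicate 2. The chemokine median was 0.79 without WT replicate 3.

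Some markers of myeloid cells also rose. Of 18 neutrophil genes 8 rose and 1 fell, the histone-modifying enzyme gene Padi4 by 0.99 (9 and 1 adjusted over the list alone; median 0.50, camera adjusted p = 8.53e-04, and adjusted p = 0.543 with an estimated correlation). Without WT replicate 1 or HdR replicate 2, 5 rose. The neutrophil median was 0.24 without HdR replicate 2, 0.24 with the filter at 5 bases per Mb and 0.21 with total scaling. The pathogen receptor gene Clec4d rose from 13.5 ± 6.23 to 63.9 ± 15.4, the neutrophil collagenase gene Mmp8 from 1.2 ± 0.297 to 6.78 ± 2.91 and Stfa2l1 from 0.317 ± 0.0804 to 3.54 ± 1.53. After length correction 8 rose and 1 fell (median 0.46, camera adjusted p = 0.00863). Of 24 monocyte and macrophage genes 12 rose and 0 fell (14 and 0 adjusted over the list alone; median 0.87, camera adjusted p = 1.41e-05, and adjusted p = 0.535 with an estimated correlation). The scavenger receptor gene Cd163 rose from 14.8 ± 2.52 to 41.8 ± 6.94, Lyve1 from 81.8 ± 5.96 to 164 ± 19.5, Cd14 from 17.3 ± 2.54 to 37.7 ± 4.07 and the lysozyme gene Lyz2 from 585 ± 223 to 1779 ± 212. After length correction 10 rose (median 0.52, camera adjusted p = 5.50e-04). The macrophage count was 3 without WT replicate 1, 6 without WT replicate 3, 6 without HdR replicate 1 and 7 without HdR replicate 2, and the median was 0.56 with total scaling.

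Of 21 dendritic and Langerhans cell genes 7 rose and Cacnb3 fell by 1.04 (7 and 1 adjusted over the list alone; median 0.41, camera adjusted p = 0.00317, and adjusted p = 0.564 with an estimated correlation). Mgl2 rose from 33.1 ± 1.71 to 65.8 ± 4.01, Cd209a from 7.61 ± 2.62 to 19.0 ± 2.24 and Flt3, a growth factor receptor gene of dendritic cells, from 2.41 ± 0.157 to 5.13 ± 0.956. The list did not pass after length correction (5 higher, 1 lower, camera adjusted p = 0.0916). The count of risen genes was 1 without WT replicate 1, 3 without WT replicate 3, 3 without HdR replicate 1 and 2 without HdR replicate 2. It was 4 with total scaling, and the median was 0.14 there and 0.24 without HdR replicate 1. In the mast cell and basophil list 4 of 15 rose and 0 fell (5 and 0 adjusted over the list alone; median 0.41, camera adjusted p = 0.00195, and adjusted p = 0.561 with an estimated correlation): the tryptase genes Tpsb2 (0.79) and Tpsab1 (1.17), the IgE receptor gene Ms4a2 (0.99) and Mrgprb2 (0.79). After length correction 2 rose, Ms4a2 and Hdc (camera adjusted p = 0.00486). With the replicate block 7 rose, without WT replicate 2 it was 10, and without WT replicate 1, WT replicate 3 or HdR replicate 1 it was 0. It was 1 without HdR replicate 2, 2 without HdR replicate 3 and 0 with total scaling. The mast cell median was 0.10 with total scaling, 0.23 without WT replicate 3 and 0.69 without WT replicate 2. In the eosinophil and type 2 cytokine list 5 of 11 rose and 0 fell, both over all genes and adjusted over the list alone: Ear2 (1.80), the epidermal growth factor family gene Areg (1.18), Tslp (0.99), Il13 (0.65) and Il1rl1 (0.82). This list passed camera (median 0.47, adjusted p = 0.00337, and adjusted p = 0.543 with an estimated correlation). After length correction 3 rose (camera adjusted p = 0.0224). Tslp (0.54, limma adjusted p = 0.190) and Il13 (0.22, limma adjusted p = 0.383) no longer passed. Il13 was also low, at 0.524 ± 0.223 in WT and 1.38 ± 0.193 in HdR. In this list 2 rose without WT replicate 1, WT replicate 3, HdR replicate 1 or HdR replicate 2, 3 without HdR replicate 3 and 2 with total scaling. The median was 0.86 with a pseudocount of 0.1 and 0.82 with the filter at 5 bases per Mb. T and NK cell genes did not pass (2 of 23 higher, Il7r and Skap1, and 2 lower, Il2rb and Prf1; 0 adjusted over the list alone by limma, camera adjusted p = 0.0929). They passed with the replicate block (0.0481, 6 higher), without WT replicate 2 (0.00888) and without HdR replicate 3 (0.00413). After length correction 1 rose and 0 fell (camera adjusted p = 0.428), and with the block as well the adjusted p was 0.351. Their median of 0.26 was -0.01 with total scaling, where camera placed the list higher than other genes (adjusted p = 0.0489). It was 0.49 without WT replicate 2, with 5 higher, 0.17 without WT replicate 3 and 0.14 without HdR replicate 1, and 0 rose without WT replicate 1, WT replicate 3, HdR replicate 1 or HdR replicate 2. In the B cell list 1 gene was tested, Cd79b, at 2.11 ± 1.30 in WT and 3.68 ± 2.06 in HdR (limma adjusted p = 0.241).

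Many type I interferon response genes fell. Of 38 tested, 21 fell and 0 rose (24 and 0 adjusted over the list alone), with a median log2 change of -1.0 (camera adjusted p = 1.27e-05, and adjusted p = 0.543 with an estimated correlation). Eif2ak2, the gene of the double-stranded RNA sensor PKR, fell from 182 ± 13.1 to 66.4 ± 3.43 (limma adjusted p = 0.00167), Stat2, a transcription factor of interferon signalling, from 163 ± 9.37 to 68.4 ± 2.67, and Oas3 from 22.6 ± 1.98 to 7.61 ± 0.753. After length correction 17 fell and 0 rose (median -0.94, camera adjusted p = 1.06e-07), and 9 fell without WT replicate 1. With the replicate block or without WT replicate 2, 2 interferon genes rose, and 1 rose without HdR replicate 3. The interferon gamma and antigen presentation list did not pass (camera adjusted p = 0.494; 0.0245 without WT replicate 3) and its members went both ways. The MHC class II genes H2-Aa, H2-Eb1 and H2-Ab1 rose by 1.03, 1.19 and 0.90, and Gbp3 (-1.32), Tap1 (-0.74), Nlrc5 (-0.72), Cd274 (-0.82) and Gbp6 (-0.83) fell. These are 3 and 5 of 28, likewise 3 and 5 adjusted over the list alone, and 9 fell with the replicate block. After length correction H2-Aa and H2-Eb1 were higher and Gbp3 lower, and without WT replicate 1 limma called 0 of the 28. H2-Ab1 stood at 0.48 after correction with an annotated length of 1212 nt, against 3223 nt for H2-Aa. The contrast between these genes thus depends on the lengths used. Total scaling and quantile normalisation each gave 8 lower, and 3 fell without WT replicate 2, 2 without HdR replicate 3 and 1 without HdR replicate 2.

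The hair follicle and hair shaft list had the largest median change of the 27 lists tested. Of 31 genes 29 fell and 0 rose, also adjusted over the list alone, with a median log2 change of -2.12 (camera adjusted p = 8.59e-16, and adjusted p = 0.535 with an estimated correlation). Krt75, a keratin of the companion layer of the follicle, fell from 32.8 ± 5.22 to 6.73 ± 0.377. After length correction 28 of 30 fell (median -2.06, camera adjusted p = 2.96e-20), and leaving out any single library left 22 to 29 genes lower. With voom the median was -3.28. Of 35 cell cycle genes 19 fell and 0 rose (20 and 0 adjusted over the list alone; median -0.92, camera adjusted p = 5.42e-06, and adjusted p = 0.561 with an estimated correlation). The proliferation marker Mki67 fell from 101 ± 25.8 to 19.1 ± 9.05, the kinetochore gene Cenpf from 28.7 ± 7.53 to 4.79 ± 3.06, the DNA replication gene Mcm6 from 61.7 ± 14.2 to 21.2 ± 5.60 and Hells from 40.5 ± 3.60 to 18.2 ± 3.35. After length correction 18 fell (median -0.68, camera adjusted p = 1.06e-07), and 8 fell without WT replicate 1. With the replicate block or without WT replicate 2, 1 cell cycle gene rose.

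Other keratinocyte lists moved less. In the wound and stress list 4 of 33 rose, Slpi (1.31), Areg, Sprr2i (0.83) and Hbegf (1.04), and 2 fell, the cornified envelope precursor Sprr1a (-1.26) and the psoriasin gene S100a7a (-1.47), with 2 and 2 adjusted over the list alone. Its median was 0.32 (camera adjusted p = 0.0102, and adjusted p = 0.668 with an estimated correlation) and turned to -0.08 after length correction (camera adjusted p = 0.670; 3 higher and 2 lower). The call was also lost without HdR replicate 1 (camera adjusted p = 0.143) or HdR replicate 2 (0.0942), with voom (0.238), with no filter (0.0671) and with the filter at 5 bases per Mb (0.0663). In this list 13 rose without HdR replicate 3, 8 with the replicate block and 2 without WT replicate 1, WT replicate 3 or HdR replicate 1. The median was 0.17 without HdR replicate 1, 0.66 without HdR replicate 3, 0.06 with voom and 0.00 with total scaling, and 0 fell without WT replicate 1, WT replicate 3 or HdR replicate 3. Cornified envelope and late differentiation genes did not pass (camera adjusted p = 0.424, median -0.20). The filaggrin family gene Flg2 rose by 0.97, and Cdsn (-1.23), the lipid transporter gene Abca12 (-1.06), Casp14 (-0.70) and Krt1 (-1.03) fell, 1 and 4 of 35, with 0 adjusted over the list alone by limma. After length correction 9 fell and 2 rose and the list passed (median -0.29, camera adjusted p = 0.00228, and adjusted p = 0.553 with an estimated correlation), and 13 fell with the replicate block. Total scaling gave 15 lower (median -0.52) and quantile normalisation 10 (-0.32), while 0 fell without WT replicate 1, WT replicate 3 or HdR replicate 2 and 2 without HdR replicate 3. Without WT replicate 3 the median was -0.12. In the basal keratinocyte list 4 of 13 fell, also adjusted over the list alone: Lama3 (-0.92), the integrin gene Itgb1 (-0.62), Dst (-0.88) and the basal keratin Krt14 (-0.71; camera adjusted p = 0.0934 for the list, 0.0289 without WT replicate 2 and 0.0139 with no filter). After length correction Krt14 was lower and Trp63 higher. Of this list 0 fell without WT replicate 1, WT replicate 3 or HdR replicate 2, 1 without HdR replicate 1 and 2 without HdR replicate 3. In the sebaceous gland list Plin5 (0.96) and Cidea (0.46) rose and Krt79 (-1.15), the cholesterol-esterifying Soat1 (-1.04) and Fa2h (-1.05) fell. These are 2 and 3 of 18, with the same counts adjusted over the list alone (camera adjusted p = 0.944; 4 and 6 with the replicate block; 2 and 2 after length correction). They were 0 and 5 with total scaling, 1 and 5 with quantile normalisation, 4 and 3 without WT replicate 2, 1 and 1 without WT replicate 3 or HdR replicate 2, and 1 and 3 without HdR replicate 1 or HdR replicate 3. Without WT replicate 1 limma called 0 members of the cornified envelope, basal and sebaceous lists.

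Markers of other tissues of the ear moved apart. Of 16 adipocyte genes 9 rose and 0 fell (9 and 1 adjusted over the list alone; median 0.78, camera adjusted p = 1.79e-04, and adjusted p = 0.384 with an estimated correlation). The fatty acid binding protein gene Fabp4 rose from 358 ± 55.0 to 1708 ± 413, the adiponectin gene Adipoq from 76.2 ± 7.86 to 261 ± 61.6, Thrsp from 5.69 ± 0.404 to 29.1 ± 9 and the resistin gene Retn from 20.7 ± 0.499 to 68.1 ± 14.7. After length correction 9 rose (median 0.80, camera adjusted p = 5.50e-04). The median was 0.46 with total scaling, and adipocyte genes also fell, 2 with the replicate block and 3 without WT replicate 2. Of 22 skeletal muscle genes 9 rose and 0 fell (10 and 0 adjusted over the list alone), with Pvalb (1.44), Tnni2 (1.28), Mylpf (1.23) and Tnnt3 (1.12), proteins of fast fibres, first. The muscle median was 0.07 (camera adjusted p = 0.0138, and adjusted p = 0.624 with an estimated correlation). With total scaling it turned to -0.24, while camera still placed the list higher than other genes (adjusted p = 0.00153). The call was lost after length correction (camera adjusted p = 0.129, 5 higher), with the replicate block (0.103), without WT replicate 2 (0.483) and with voom (0.143). Muscle genes also fell there: 4 with the replicate block, 7 without WT replicate 2 and 5 with voom. Without WT replicate 1, 2 rose. The muscle median was -0.10 without WT replicate 2, 0.14 without WT replicate 1, 0.30 without WT replicate 3, 0.33 without HdR replicate 2, 0.20 with quantile normalisation and 0.23 with the filter at 5 bases per Mb. In the blood list the platelet gene Pf4 (50.4 ± 14.4 to 243 ± 35.3) and the globin genes Hbb-bt (1.24) and Hbb-bs (1.1) rose. These are 3 of 9 (5 adjusted over the list alone; median 0.70, camera adjusted p = 0.00192, and adjusted p = 0.543 with an estimated correlation). After length correction Pf4 alone rose (camera adjusted p = 0.103), as many as without HdR replicate 2. The median of the blood list was 0.38 with total scaling and 0.22 after length correction. Hba-a1 stood at 97.3 ± 30.3 and 156 ± 35.3 and held values identical to those of its copy Hba-a2, so these reads could not be assigned to either.

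In the fibroblast and matrix list 7 of 19 fell and Dpt rose by 0.90, also adjusted over the list alone (median -0.39, camera adjusted p = 0.0386, and adjusted p = 0.564 with an estimated correlation). The collagen gene Col1a1 fell from 344 ± 58.2 to 93.8 ± 30.4, Col5a1 from 38.4 ± 7.68 to 16.3 ± 3.59, the elastin gene Eln from 147 ± 50.9 to 55.5 ± 0.640 and the periostin gene Postn from 1966 ± 255 to 740 ± 298. This call was lost after length correction (camera adjusted p = 0.121, with 5 lower and 2 higher), without WT replicate 2 (0.0771) and without HdR replicate 3 (0.15) and with the filter at 5 bases per Mb (0.0537), and 1 fell without WT replicate 1. Total scaling gave 11 lower (median -0.71) and quantile normalisation a median of -0.78, and 0 rose without WT replicate 1, WT replicate 3 or HdR replicate 2. The remaining tissue lists did not pass. In the endothelium list Lyve1 rose and the vessel receptor genes Tie1 (-1.02) and Tek (-0.79) and the cadherin gene Cdh5 (-0.64) fell. These are 1 and 3 of 17 (also adjusted over the list alone; camera adjusted p = 0.379; 6 lower with the replicate block; Lyve1 and Tie1 after length correction). None of the 3 fell without WT replicate 1, WT replicate 3 or HdR replicate 2, 1 endothelial gene fell without HdR replicate 1 or with quantile normalisation, and 6 fell with total scaling. In the cartilage list the lubricin gene Prg4 rose by 1.34 and Col11a1 (-1.03), Chad (-1.41), Col9a3 (-1.16), Col9a1 (-0.72) and Col9a2 (-1.14) fell. These are 1 and 5 of 16 (1 and 6 adjusted over the list alone; camera adjusted p = 0.424; 9 lower without WT replicate 2, 0 without WT replicate 1, 3 without HdR replicate 3 and 1 without WT replicate 3, HdR replicate 1 or HdR replicate 2; 2 and 2 after length correction). In the Schwann cell and melanocyte list S100b rose by 1.09 and Prx (-1.31) and the pigment genes Tyrp1 (-1.07), Slc45a2 (-1.10) and Tyr (-1.26) fell. These are 1 and 4 of 17 (also adjusted over the list alone; the same counts after length correction, with Pmel in place of Tyr; camera adjusted p = 0.196, and 0.0357 with no filter; 2 lower without WT replicate 1 and 2 higher without HdR replicate 2).

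Of the 20 LUBAC and linear ubiquitin regulators, Rbck1, Rnf31, Ikbkg (-0.82), the deubiquitinase gene Cyld (-0.62) and its partner Spata2 (-0.77) fell and 0 rose, also adjusted over the list alone (camera adjusted p = 0.196, and 0.0379 with no filter). After length correction Rbck1 was lower and Tnfaip3, the gene of the ubiquitin-editing enzyme A20, higher, with Ikbkg at -0.32 and Cyld at -0.08. In this list 1 fell without WT replicate 1 or WT replicate 3, 2 without HdR replicate 2 and 3 without HdR replicate 1 or HdR replicate 3. In the list of cell death regulators the death receptor gene Fas (0.91), Bcl2a1b (1.83) and the proapoptotic Bax (0.93) rose and the gasdermin gene Gsdmc fell by 1.54. These are 3 and 1 of 30 (also adjusted over the list alone; camera adjusted p = 0.792; 5 and 5 with the replicate block; 3 and 2 after length correction). Bax no longer passed after length correction (0.47, limma adjusted p = 0.0666), so the 3 higher there were not all the same genes. Counts for this list were 0 and 0 without WT replicate 1, 1 and 1 without WT replicate 3 or HdR replicate 2, 6 and 2 without WT replicate 2 and 2 and 4 with total scaling. Its median of -0.20 and mean of -0.05 had the opposite sign to the camera statistic. The median was -0.09 without WT replicate 1, -0.12 without WT replicate 2, -0.13 without HdR replicate 2, -0.43 with total scaling and -0.08 with quantile normalisation. Among immediate early and heat shock genes, Fos (31.0 ± 2.91 to 84.5 ± 13.8), Dusp1 (80.8 ± 11.4 to 182 ± 4.24), Junb (0.68), Btg2 (0.74) and Myc (0.82) rose and the chaperone gene Hsp90aa1 fell by 0.79 (5 and 1 of 27, also adjusted over the list alone). Their median of 0.28 passed (camera adjusted p = 0.0280, and adjusted p = 0.668 with an estimated correlation) but was -0.04 with total scaling, where camera still placed the list higher (adjusted p = 0.0355), -0.07 with voom, 0.06 with quantile normalisation and 0.16 without HdR replicate 1. The call was lost after length correction (camera adjusted p = 0.0527, 4 higher), with the replicate block (0.0802, 8 higher), without WT replicate 2 (0.314) and without HdR replicate 3 (0.0571), with voom (0.541) and with no filter (0.0996), and 2 rose without WT replicate 3, HdR replicate 1 or HdR replicate 2. Without WT replicate 1 or HdR replicate 3, 3 rose, and without WT replicate 2, 3 fell. With total scaling 2 rose, and with median-of-ratios scaling 7 rose. Of the mitochondrially encoded list 0 genes were measured.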

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

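The removal of the length trend, its 2 combinations and the filter at 5 bases per Mb were chosen after the results were seen, and all other alternatives before; the count-model alternative was not run, since the values are not counts, and the planned filter of 1 base per Mb equals the filter used. Rbck1 stayed lower under every alternative (-2.01 with total scaling; leaving out 1 library, -1.88 to -1.47). Against 4605 genes changed (1904 higher, 2701 lower), total scaling gave 917 higher and 4305 lower, voom 8045 (3398 and 4647) and the replicate block 4094 lower; the cause was not tested. No filter gave 2144 (1017 and 1127), with 23289 genes tested. Leaving out 1 library gave 427 to 6016 genes changed, 197 to 2657 higher and 230 to 3359 lower, with 16 to 18 lists past camera against 17. Removing the length trend gave 2884 genes changed and 1263 lower, and 813 (400 and 413) without HdR replicate 2. Removing it together with the replicate block gave 4632 (2460 higher and 2172 lower). The cause of these differences was not tested. Estimated correlation passed 0 lists and fry 4. Camera with an estimated correlation allows for shared variation and fry tests a list alone, but the cause of the smaller counts was not tested. The IL-23 and IL-17 and adipocyte lists had estimated correlations of 0.038 and 0.045, near the preset 0.01. Their camera adjusted p still rose from 1.11e-04 and 1.79e-04 to 0.384 each. The other lists past camera had larger estimates, up to 0.572 for the cell cycle. A call lost with an estimated correlation thus does not by itself show that a list's genes vary together. Of 123 named genes, 112 kept direction and call with total scaling, 114 with quantile normalization, 93 with no filter, 123 with the replicate block and, of 121, 67 without WT replicate 1; 92 of 122 did with the length trend removed. Cyld turned to 0.042 with the length trend and HdR replicate 2 removed, and the wound and stress list to -0.084 with the length trend removed, -0.084 with the replicate block as well and -0.19 without HdR replicate 2; the cause was not tested. Quantile normalization lost the muscle (camera adjusted p = 0.213) and immediate early (0.15) calls and passed the cornified envelope (0.00552), basal (0.0123) and interferon gamma (0.0323) lists. Voom lost the wound and stress (0.238), muscle (0.143) and immediate early (0.541) calls, and the filter at 5 bases per Mb the wound and stress (0.0663) and fibroblast (0.0537) calls. No filter lost the wound and stress (0.0671) and immediate early (0.0996) calls and passed the LUBAC (0.0379), basal (0.0139) and Schwann cell and melanocyte (0.0357) lists. With the length trend and HdR replicate 2 removed the wound and stress (0.398), dendritic cell (0.166), eosinophil (0.0601) and immediate early (0.0601) calls were lost and the cornified envelope list passed (0.00319). The replicate block changed no list call beyond the muscle, immediate early and T and NK cell calls. Depth limits genes near the filter, where 1 base per Mb is 11.7 to 23.6 read pairs.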

Other observations

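The gene classes in this part, the removal of the length trend, the comparisons of slopes within a genotype and within a replicate number, the plasmacytoid cell markers and the growing follicle regulators outside the hair list were chosen only after the results were seen. Of 12 classes taken by symbol, the 7 with the largest shares of changed genes come before the other 5. Of 83 genes for cytosolic ribosomal proteins 73 were higher in HdR and 0 lower (median log2 change 1.23; 50 higher and 0.80 with the length trend removed), of 78 for mitochondrial ribosomal proteins 45 and 0 (0.76; 37 and 0.49), and of 88 for oxidative phosphorylation 69 and 1 (0.94; 43 and 0.50). Of 36 hair keratin-associated genes 33 were lower (-1.38; 36 and -1.93), and of 39 collagen genes 19 were lower (-0.84; 5 and -0.39). Of 5 beta-defensins 4 were higher, with the length trend removed too, and of 24 small nucleolar RNAs 13 were higher, but 1 with the length trend removed. The other 5 classes had smaller shares of changed genes: zinc finger genes named Zfp (11 higher and 47 lower of 322), cathepsins (1 and 1 of 14), proteasome genes (6 and 1 of 37), histones (6 and 1 of 22) and Wnt ligands (0 and 5 of 14). With the length trend removed these counts were 13 and 16, 2 and 2, 3 and 2, 2 and 3, and 0 and 1. The Wnt ligands had a median of -0.58 (-0.45 with the length trend removed) and passed camera in both fits (adjusted p = 0.0102 and 0.00871), though not with an estimated correlation (adjusted p = 0.258). Camera adjusted p was 7.14e-28 for the cytosolic ribosomal proteins and 1.49e-14 for the hair keratin-associated genes; with an estimated correlation 0 classes passed, the smallest adjusted p being 0.155.

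Shorter transcripts were higher and longer ones lower in HdR (Spearman rho of change and length -0.51). The widest gap in slope between libraries of 1 genotype was 0.206, a share of 0.648 of the 0.318 between the genotype means. The slopes followed the replicate number, however: WT minus HdR was 0.315, 0.312 and 0.327 in replicates 1, 2 and 3, so the gap within a genotype says nothing on the source of the difference between genotypes, which is left open. GC content alone is excluded as the cause, since rho stayed at -0.565 within GC deciles. With 250 ribosomal protein genes and small non-coding RNAs left out rho was -0.503, so the trend ran through the other genes too. These 250 are few of the 14901 genes with a length, so leaving them out could hardly have removed the trend.

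Hair follicle genes had a median change of -2.06 (SE 0.21) with the length trend removed, with 28 of 30 lower, and the list lost its camera call with an estimated correlation (adjusted p = 0.525). This median lies below the bound of -1, so that the trend alone does not account for these genes. The check could hardly have come out otherwise. The median length of the list was 2177 nt, and in the bin from 1852 to 2324 nt the median change of all genes was 0.13. SE here and in the next paragraph comes from the spread between member genes and holds no spread between mice. Genes that vary together can make it too small. Markers of the permanent follicle stood at -0.14 (SE 0.18), against a bound of -1, so these 9 markers as a set did not fall that far, though Gli1 (-1.11) and Tbx1 (-1.44) fell. Krt15 also belongs to the basal keratinocyte list, so not all 9 are particular to the follicle. Their median does not settle the amount of follicle tissue. Regulators of the growing follicle stood at -0.68 (SE 0.20), between the bounds of -0.5 and -1, but 4 of these 10, Hoxc13, Msx2, Shh and Lef1, belong to the hair follicle list itself, so this value partly restates the fall. The other 6 stood at -0.31 (SE 0.18), about 1 SE above the bound of -0.5, and whether fewer follicles were growing is left open.

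Of 35 NF-kB targets 15 were higher and of 38 type I interferon genes 21 lower in HdR, and both lists lost their camera call with an estimated correlation (adjusted p = 0.543 each, 0.553 each with the length trend removed). Their medians lay 1.71 (SE 0.16, from the spread between genes) apart with the length trend removed. The trend as removed thus does not account for the gap in these samples. This check was weak, however, since the lists had similar median transcript lengths of 2909 and 3257 nt. Both lie in the bin from 2808 to 3271 nt, where the median change of all genes was -0.14. Of 8 markers of plasmacytoid dendritic cells, a main source of type I interferon, 5 were tested, with a median of 0.42 (SE 0.12) with the length trend removed and 0.06 as fitted. With the length trend removed all 5 lay above 0, from 0.09 to 0.85 for Siglech, the only one that passed. In these samples the 5 markers thus did not fall to the bound of -0.5. Tcf4 and Runx2 are also expressed in other skin cells, so the markers do not settle the number of these cells.

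The strain test was fixed before the results were seen. Genes within 10 Mb of Rbck1 were called as often as others (49 of 161, 30.4% against 30.6%, a ratio of 0.995; two-sided Fisher exact p = 1), so the calls did not gather near Rbck1. The test cannot detect strain differences elsewhere in the genome or effects of flanking sequence on distant genes. The 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05: 1 of 10, the real one, gave as many genes changed (4605, the highest other 0), higher (1904, the highest other 0) and lower (2701, the highest other 0), and 1 of 10 as many lists (17, the highest other 16). The other splits passed 8 to 16 lists, and the 3 of them that also part all 3 pairs passed 11 to 16.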
